A study of Mus musculus with 33 samples.

How the data were processed

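The series labels list 33 samples of mouse: 6 for chromatin accessibility, 24 for bulk RNA and 3 for single-cell RNA. The 3 single-cell libraries are used here, and the other samples are not used here. Per the labels, the cells came from the colon of adult mice of both sexes, with the muscle layer removed, the epithelium released with EDTA and the mesenchyme digested with collagenase. The whole mesenchyme cells were sorted as EpCAM-negative and CD45-negative (genotype given as control), and the GFP-low cells were sorted by the level of a nuclear GFP reporter at the Pdgfra locus. The gate limits are not given in the sources used here. Per the labels, 8000 cells were loaded per library on a 10x Genomics 3' kit.

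Each library is a matrix of UMI counts as deposited, made by the authors with Cell Ranger 3.0.2 on the mm10 mouse genome, per the file headers and the labels, with 31053 genes and 6794880 barcodes before any cell calling. The values were checked to be whole numbers. The reporter has no row of its own in the matrices, so GFP transcripts could not be counted.

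A barcode was kept as a cell with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. At least 1000 UMIs were found in 6902 barcodes of whole mesenchyme, 4861 of GFP-low replicate 1 and 6035 of GFP-low replicate 2, and 6793, 4834 and 6025 passed all 3 limits. Scrublet (in scanpy 1.11.5, expected doublet rate 6%) marked 2, 3 and 3 cells, or 0.029%, 0.062% and 0.05%. It has therefore not worked as a doublet filter, and an alternative removed the 6% of cells with the highest scores. Among barcodes that passed, the median number of genes was 1879, 2458.5 and 2350, and the median mitochondrial share 4.08%, 3.22% and 1.81%.

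Genes were divided at random into a clustering part of 15489 genes and a held-out part of 15564 genes. All 112 marker genes of 18 cell types went to the first part and all 222 genes of the 17 lists to the second. The 17644 cells were clustered together, without integration, on 2000 variable genes of the clustering part (30 principal components, 15 neighbours, Leiden resolution 1, seed 1; leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9). A cluster was named after the cell type with the most markers among its 10 leading genes or, failing that, elevated 1.5-fold with at least 20 CPM. At least 3 elevated markers were needed, and a cluster could stay unnamed where another type had as many or more elevated markers, or where it was very shallow without a leading marker. Of the 25 clusters 3 stayed unnamed, among them cluster 14 at 0.234 of the median depth of its libraries; clusters 7 and 9, at 0.392 and 0.359 and also without a leading marker, were named. Names mean resemblance. Stress, immune or technical genes led several named clusters: Ifit1, Myc and Mt2 cluster 0, Cxcl2 and Saa3 cluster 1, Socs1, C3 and Ccl7 cluster 3, mitochondrial genes cluster 9, and Xist and Tsix cluster 7, whose cells were also shallow.

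Counts were summed per library and class, with at least 20 cells per sum. Cd81-high and Cd81-low sums were compared on held-out genes with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood test, library as block, Benjamini-Hochberg adjustment, threshold 0.05). The common biological coefficient of variation was 0.1017. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01). The alternatives for lists were camera with an estimated correlation and fry. The 17 lists were BMP ligands, BMP antagonists, BMP receptors and Smads, BMP response genes, Wnt ligands, R-spondins, secreted Wnt inhibitors, Wnt response genes, other growth factors, Hedgehog response, TGF-beta and activin genes, collagens, matrix glycoproteins, chemokines and cytokines, complement, retinoid metabolism and dissociation response. They, the markers, the tests and most alternatives were chosen before the data were examined.

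Comparisons with 1 library on a side have no test, except the test of whether class differences differ between groups, which takes its spread from the GFP-low libraries. They give CPM with exact Poisson intervals, shares with exact binomial intervals and list medians beside 10000 random lists matched on expression, with a floor of 3 counts for genes at 0. A gene stood apart between libraries at 2-fold outside both GFP-low values. The genes named were 17 fixed beforehand, up to 3 per list with the largest changes among those that passed in the same direction in every library, and the 5 largest changes in each direction outside the lists with at least 50 CPM. Some genes that this rule names are not reported here. In comparisons without a test they were the same 17 and up to 3 per list at least 4-fold apart with at least 10 UMIs. The comparison of a Pi16-positive cluster, the test of whether class differences differ between groups, the doublet score alternative and the alternatives by sex transcripts were added after the data had been seen.

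The alternatives changed 1 choice at a time, except that classes set by a Cd81 UMI also used cells thinned to 1000 UMIs: UMI and mitochondrial limits, clustering resolution, clustering on all genes or per library, equal cell numbers, cells thinned to 1000 UMIs, RLE factors, DESeq2 1.42.0, no count filter, no library block, each library left out, GFP-low libraries only, all genes tested, and classes set by a Cd81 UMI in thinned cells. Leaving out whole mesenchyme and using the GFP-low libraries only are the same fit. On simulated counts with the fitted common coefficient of variation for every gene (6474 genes, 200 of them changed), the edgeR test recovered 52.2% of genes changed 1.5-fold, 92.5% at 2-fold and 100% at 4-fold, with 9 false calls, and made 0 calls with no changed gene. Unequal spread between genes and the forming of classes were not simulated, so these rates may not hold for the data.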

Results

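Mesenchymal cells of the adult mouse colon were profiled by droplet single-cell RNA sequencing, in which each captured transcript is counted once through a unique molecular identifier (UMI). There were 3 libraries in 2 groups. The whole mesenchyme library (1 library) held cells sorted as negative for the epithelial protein EpCAM and the leukocyte protein CD45. The GFP-low libraries (2 replicates) held cells sorted for a low level of a nuclear green fluorescent protein made from the Pdgfra locus, which encodes PDGF receptor alpha, a receptor of gut fibroblasts. The whole mesenchyme library held 41863444 UMIs, GFP-low replicate 1 held 39190629 and GFP-low replicate 2 held 52313765. After filtering there were 6791, 4831 and 6022 cells in that order, with medians of 4429, 6443 and 7022.5 UMIs per cell. Nothing in the labels says whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Within the Cd81-high class, described next, the counts of the GFP-low replicates differed beyond sampling noise (chi-square per degree of freedom of 191 over 12885 genes), as libraries prepared separately from 1 animal also would. Counting intervals are at the 95% level and cover counting error only.

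The first comparison asked how the cell classes were distributed between whole mesenchyme and GFP-low sorted cells. Fibroblasts with Cd81 transcripts made up 8.57% of the cells of whole mesenchyme (exact binomial interval 7.92 to 9.26%), against 72.1% (70.8 to 73.4%) in GFP-low replicate 1 and 69.1% (67.9 to 70.2%) in GFP-low replicate 2. Lamina propria fibroblasts rich in Adamdec1 and with few Cd81 transcripts made up 48.2% (47.0 to 49.4%), 24.0% (22.8 to 25.3%) and 22.5% (21.4 to 23.5%). Subepithelial cells with the highest Pdgfra level, which resembled telocytes, made up 23.2% (22.2 to 24.2%) of whole mesenchyme, and 0.435% (0.269 to 0.664%) and 0.232% (0.127 to 0.390%) of the GFP-low replicates. Of the cells of both fibroblast classes, the Cd81-high class took 15.1% (14.0 to 16.3%) in whole mesenchyme, 3483 of 4644 cells (73.7 to 76.2%) in GFP-low replicate 1 and 75.5% (74.3 to 76.6%) in GFP-low replicate 2. With 1 library in the first group there was no test, and the sorts set these shares in part: the GFP gate selects on the Pdgfra reporter, and the sort of the whole mesenchyme library did not.

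The class names mean that cells resembled a type by marker genes fixed beforehand. Cd81, which encodes a tetraspanin surface protein, stood at 475, 571 and 411 CPM (UMI counts scaled to the total of the class) in the Cd81-high class of whole mesenchyme, GFP-low replicate 1 and GFP-low replicate 2, and at 20.8, 29.1 and 24.6 CPM in the Cd81-low class. Adamdec1, a metalloprotease gene of lamina propria fibroblasts, stood at 618, 314 and 234 CPM in the Cd81-high class and at 13396, 11009 and 12657 CPM in the Cd81-low class. Scara5, one of the markers fixed for the Cd81-low class, went the other way, with 268, 264 and 237 CPM in the Cd81-high class and 12.3, 14.1 and 13.5 CPM in the Cd81-low class. After every cell was thinned to 1000 UMIs, 6.35% (5.60 to 7.17%) of the fibroblasts of both classes in whole mesenchyme held a Cd81 UMI, against 31.4% (30.1 to 32.8%) and 25.4% (24.2 to 26.6%) in the GFP-low replicates. No cell was left out by the thinning, and the unthinned shares were 17.0%, 68.0% and 68.5%. By class, the thinned shares were 33.8%, 41.1% and 32.8% in Cd81-high cells and 1.47%, 2.41% and 2.66% in Cd81-low cells, whose median depths were 5618, 6245 and 7545 UMIs and 5423.5, 6906 and 6480 UMIs.

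Cells of the vessel wall, nerves and muscle were found mainly in whole mesenchyme, which was not gated on GFP. Blood endothelium counted 795 cells (11.7%) there, and 1 and 2 cells in the GFP-low replicates. Smooth muscle or myofibroblasts made up 2.36% of whole mesenchyme, pericytes 1.21%, glia 0.957% and lymphatic endothelium 0.898%. T or innate lymphoid cells counted 10 cells in whole mesenchyme, 82 in GFP-low replicate 1 and 36 in GFP-low replicate 2, and B or plasma cells 12, 21 and 23. Clusters that could not be named held 2.58%, 1.22% and 7.11% of the cells.

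**Figure D1:**
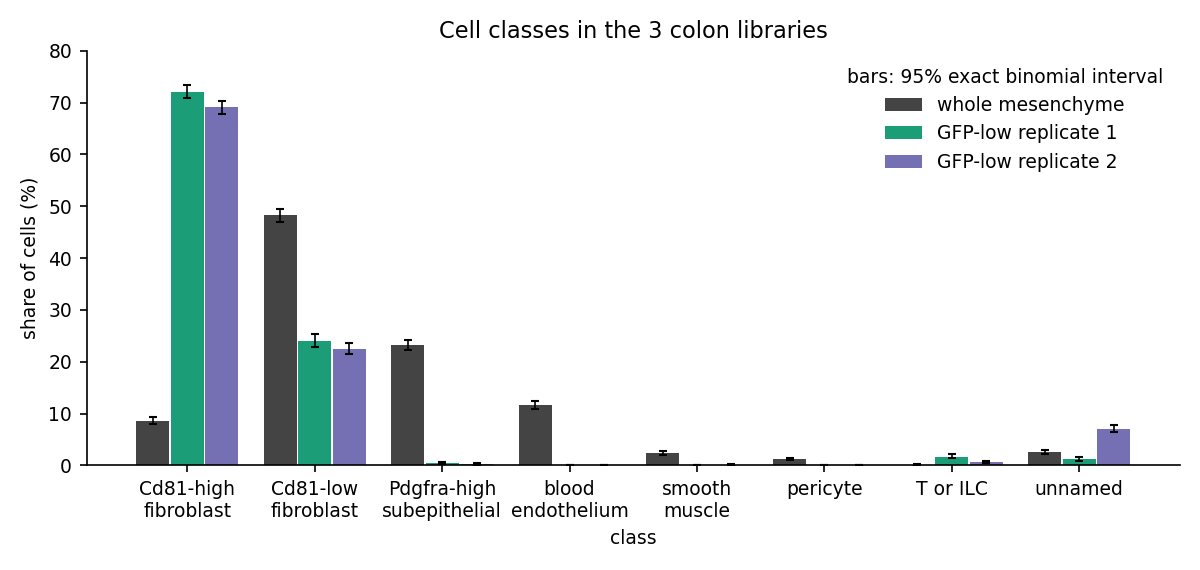
Share of cells (%, vertical axis) in each class (horizontal axis) of whole mesenchyme and GFP-low replicates 1 and 2, with exact binomial 95% intervals. The Cd81-high class lies at 8.57% in whole mesenchyme and at 72.1% and 69.1% in the GFP-low libraries, and the Pdgfra-high class lies at 23.2% against 0.435% and 0.232%.

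The second comparison set Cd81-high against Cd81-low fibroblasts, classes formed by clustering, while the series sorts its Pdgfra-low cells by CD81. Cd81-high fibroblasts carried far more transcripts of the BMP antagonist genes Grem1, Chrdl1 and Fst and of 3 R-spondins, and Cd81-low fibroblasts far more of Bmp5, Bmp7 and Wnt4. With classes set by a Cd81 UMI in thinned cells, Chrdl1, Fst, Rspo1, Rspo2 and Rspo3 no longer passed. Their log2 differences there were 0.94, 0.09, 0.34, 0.36 and 0.32. Grem1, Bmp5, Bmp7 and Wnt4 did not lose their calls. That setting left most cells of the Cd81-high class on the other side, since only 33.8%, 41.1% and 32.8% of them held such a UMI. Grem1, a secreted BMP antagonist (ENSMUSG00000074934), was higher in the Cd81-high class by 2.11 on the log2 scale (SE 0.24, adjusted p = 1.38e-04, n = 3 libraries, edgeR quasi-likelihood test), at 2564, 2235 and 3127 against 383, 894 and 650 normalised CPM in whole mesenchyme, GFP-low replicate 1 and GFP-low replicate 2. Wnt4, a Wnt ligand (ENSMUSG00000036856), was lower in the Cd81-high class by a log2 difference of -5.80 (SE 0.33, adjusted p = 1.79e-06), at 9.68, 1.89 and 3.59 against 155, 175 and 233 normalised CPM. Of 6474 genes tested, none of which had been used to form the clusters, 947 rose and 988 fell in the Cd81-high class relative to the Cd81-low class, and 1907 of these 1935 went the same way in all 3 libraries, among them every gene named below that passed. The clusters came from the same cells, so tested genes that vary with the clustering genes differ in part by construction. The p-values take the classes as given. Below, "rose" and "fell" describe Cd81-high relative to Cd81-low cells, the values are log2 differences, and adjusted p-values are Benjamini-Hochberg values of that edgeR test unless another test is named.

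Of 11 BMP antagonists tested, 7 rose, 1 fell and 3 did not pass, and 7 rose and 2 fell when adjusted over the list alone. Besides Grem1, Chrdl1, a chordin-like antagonist, rose by 4.03 (SE 0.18) and Fst, whose product follistatin binds activins and BMPs, by 3.69 (SE 0.25). The list passed camera, a test of a list against the other genes (adjusted p = 6.25e-05), and did not with an estimated correlation (adjusted p = 0.532 with an estimated correlation). BMP ligands went both ways, with 2 of 9 rising and 5 falling, the same counts when adjusted over the list alone. Bmp2 (-0.97, SE 0.11), Bmp4 (-1.14, SE 0.13), Bmp5 (-3.52, SE 0.12) and Bmp7 (-4.87, SE 0.50) fell, and the growth and differentiation factor genes Gdf6 (4.77, SE 0.26) and Gdf10 (4.00, SE 0.22) rose. The size for Bmp7 was -5.87 without whole mesenchyme and -4.18 without GFP-low replicate 2, that for Gdf6 5.48 without GFP-low replicate 2, and that for Fst 4.30 without whole mesenchyme. Bmp3 did not pass, at 0.57 (SE 0.43, adjusted p = 0.377) on 47 and 59 UMIs. The ligand list did not pass camera (adjusted p = 0.405). It passed as lower without the whole mesenchyme library (adjusted p = 0.0372; over all settings 3.00e-04 to 0.815).

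The receptor and response genes showed no common direction. Of 11 BMP receptors and Smads, 1 rose and 3 fell, also when adjusted over the list alone. Acvr2a, a type II receptor gene, rose by 0.71 (SE 0.14), and Smad9 (-1.86, SE 0.18) and the co-receptor gene Eng (-0.62, SE 0.09) fell; without whole mesenchyme 3 rose. Of 10 BMP response genes, 4 rose and 4 fell, also when adjusted over the list alone. Msx1, a homeobox gene, rose by 1.88 (SE 0.16), while Atoh8 (-1.96, SE 0.24), Id4 (-0.94, SE 0.14) and Id1 (-0.51, SE 0.16, adjusted p = 0.0436) fell. Id3, an inhibitor of DNA binding as are Id1 and Id4, did not pass at 0.15 (SE 0.24, adjusted p = 0.700). Id1 lost its call without GFP-low replicate 1 (-0.25) or replicate 2 (-0.52), and Id3 gained one without whole mesenchyme (0.54). Id1 hardly differed within whole mesenchyme, at 39.4 against 39.9 normalised CPM. Its call was also lost with DESeq2, clustering resolution 2, clustering on all genes and equal cell numbers, among other settings. Camera gave adjusted p = 0.771 for both lists. For the receptors the median (0.14) and the mean (-0.11) differed in sign and the test pointed down. For the response genes the median (-0.10) and mean (-0.02) lay below 0 and the test pointed up.

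All 3 R-spondins tested rose, also when adjusted over the list alone: Rspo1 by 2.02 (SE 0.23), Rspo2 by 1.91 (SE 0.35) and Rspo3 by 1.53 (SE 0.12). R-spondins amplify Wnt signalling through LGR receptors, and the list was too short for camera. Of 10 Wnt ligands, 3 rose and 7 fell, also when adjusted over the list alone. Wnt10b rose by 4.40 (SE 0.36) on 265 against 7 UMIs. Wnt2 (-1.17, SE 0.21), Wnt2b (-0.45, SE 0.10) and Wnt5a (-0.44, SE 0.12, adjusted p = 0.0249) fell with Wnt4. Wnt16 also fell, with 2 UMIs in Cd81-high and 42 in Cd81-low cells, a Cd81-low to Cd81-high ratio of 34.9 (counting interval 9.09 to 298). The ligand list did not pass camera (adjusted p = 0.420) and passed as lower without whole mesenchyme (adjusted p = 0.0318; over all settings 0.0227 to 0.924). Without GFP-low replicate 2 only 3 of 9 Wnt ligands fell. Wnt16 fell by 5.59 on the log2 scale without GFP-low replicate 1, against -4.95 with all libraries. Leaving out 1 library ended 3 of these calls. Wnt5a lost its call without whole mesenchyme (-0.34) or GFP-low replicate 2 (-0.43). Wnt2 lost it without GFP-low replicate 1 (-0.70) and Wnt2b without GFP-low replicate 2 (-0.36). The calls of Wnt5a and Wnt2b were also lost with all libraries kept, with DESeq2 and with thinned cells, among other settings. With DESeq2 4 of 10 Wnt ligands fell, with thinned cells 3 of 8 and with equal cell numbers 4 of 8.

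The secreted Wnt inhibitors divided between the classes, with 2 of 6 rising and 3 falling, also when adjusted over the list alone. Sfrp4 rose by 4.21 (SE 0.14) and Dkk2 by 3.08 (SE 0.66, 109 against 5 UMIs). Frzb fell by 5.49 on the log2 scale (SE 0.22), as did Sfrp1 (-1.39, SE 0.12). These genes encode secreted proteins that bind Wnts or, for Dkk2, a Wnt co-receptor. Of 6 Wnt response genes, none rose and 1 fell, Tcf7 (-3.29, SE 0.44), and 1 rose and 2 fell when adjusted over the list alone. Tcf7 stood at -3.91 without GFP-low replicate 1 and -2.41 without GFP-low replicate 2. Without GFP-low replicate 2, 1 of 5 inhibitors rose, and without whole mesenchyme 1 of 6 Wnt response genes rose. Camera gave adjusted p = 0.474 for the inhibitors, pointing down against a median of 0.00 and a mean of 0.07, and adjusted p = 0.771 for the response genes, whose median (0.07) and mean (-0.36) differed in sign.

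**Figure D2:**
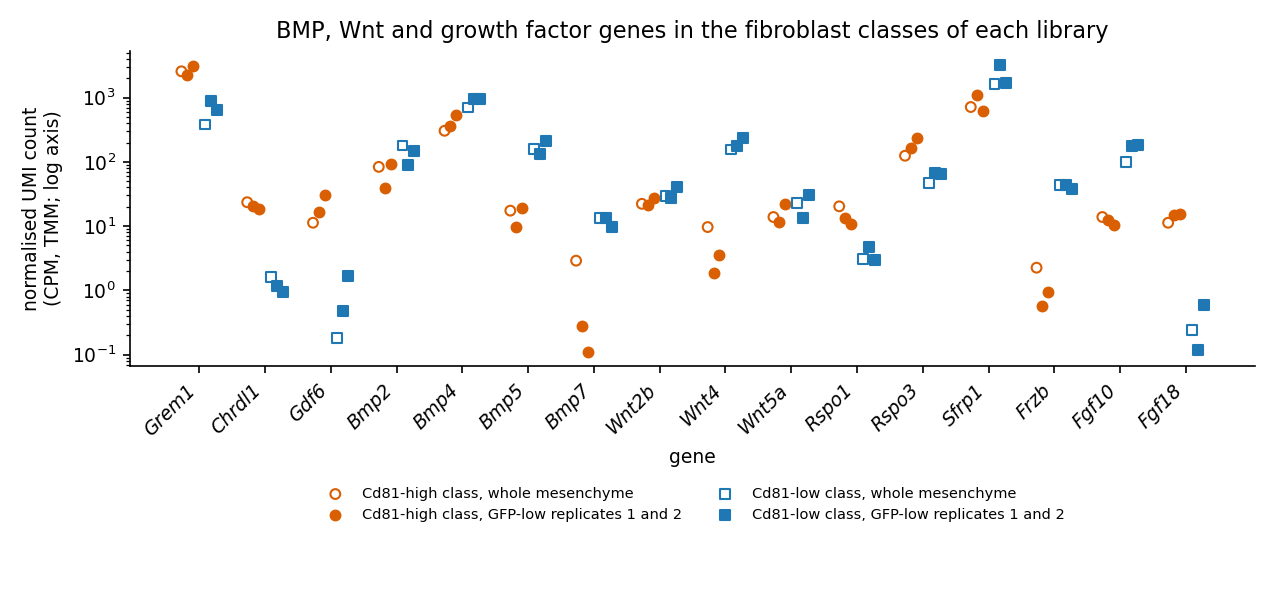
Normalised UMI count (CPM, log axis) of 16 BMP, Wnt and growth factor genes (horizontal axis) in Cd81-high (circles) and Cd81-low (squares) fibroblasts, 1 point per library, open for whole mesenchyme and filled for the GFP-low replicates. Grem1 lies at 2235 to 3127 CPM in the Cd81-high class and 383 to 894 CPM in the Cd81-low class, and Wnt4 at 1.89 to 9.68 against 155 to 233 CPM.

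Other growth factors mostly rose, with 11 of 19 rising and 4 falling, and 12 and 4 when adjusted over the list alone. Fgf18 rose by 5.43 (SE 0.30) on 774 against 10 UMIs and Fgf9 by 4.02 (SE 0.30; 4.71 without whole mesenchyme), while Fgf10, a fibroblast growth factor of mesenchyme that acts on epithelium, fell by 3.76 on the log2 scale (SE 0.19). The list did not pass camera (adjusted p = 0.118) and passed it without GFP-low replicate 1 (adjusted p = 0.0495; over all settings 0.0108 to 0.962). Of 9 Hedgehog response genes, 2 rose and 3 fell, and 3 and 3 when adjusted over the list alone. Hhip, a Hedgehog-binding protein gene, rose by 3.14 (SE 0.12), and Foxf2 (-2.09, SE 0.14) and Ptch1 (-1.42, SE 0.12), the gene of a Hedgehog receptor, fell. Gli1, a transcription factor of the pathway, did not pass at 0.16 (SE 0.11, adjusted p = 0.321). Of 11 TGF-beta ligands, receptors and activin genes, 5 rose and 1 fell, also when adjusted over the list alone. Tgfb3 rose by 0.95 (SE 0.11), Ltbp2 by 3.32 (SE 0.72, 43 against 6 UMIs), and Ltbp1 (-1.03, SE 0.11) fell. Of the TGF-beta list, 2 of 10 rose without GFP-low replicate 1, 3 of 11 without GFP-low replicate 2, and 2 of 10 fell without whole mesenchyme. Without GFP-low replicate 2, 1 of 9 Hedgehog response genes rose. Camera gave adjusted p = 0.991 for the Hedgehog list, pointing down with its mean against a median of 0.04, and adjusted p = 0.474 for the TGF-beta list.

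Matrix genes went both ways. Of 18 collagens, 3 rose and 9 fell, and 4 and 9 when adjusted over the list alone. Col8a1 rose by 4.18 (SE 0.12), and Col15a1 (-3.00, SE 0.16), a basement membrane zone collagen, and Col12a1 (-2.38, SE 0.13) fell. Of 20 laminins, fibulins and other glycoproteins, 8 rose and 4 fell, and 8 and 5 when adjusted over the list alone. The largest named changes there were falls, of the tenascin gene Tnc (-3.08, SE 0.17), the laminin chain gene Lama5 (-3.07, SE 0.37, 13 against 137 UMIs) and the nidogen gene Nid2 (-2.54, SE 0.21). Camera gave adjusted p = 0.405 for both lists, and for the glycoproteins it pointed up with the median (0.14) while the mean lay at -0.04. Of 9 retinoid genes, 2 rose and 3 fell, and 3 and 3 when adjusted over the list alone (camera adjusted p = 0.232, pointing down with the mean of -0.07 against a median of 0.19). Over all settings (camera or fry) adjusted p ran from 0.0312 to 0.8185 for the retinoid list and from 3.00e-04 to 0.817 for the collagens. Both lists thus passed under some settings. Rdh10 (-2.66, SE 0.10) and Aldh1a3 (-2.56, SE 0.11), both enzymes of retinoic acid synthesis, fell. Without GFP-low replicate 1 or without GFP-low replicate 2, 1 retinoid gene rose.

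Complement genes rose together: 9 of 10 rose and none fell, and all 10 rose when adjusted over the list alone. C3, the central complement component, rose by 2.29 (SE 0.15), from 1349, 1248 and 1121 to 6122, 7544 and 4773 normalised CPM in whole mesenchyme, GFP-low replicate 1 and GFP-low replicate 2. C7, a component of the terminal complement complex, rose by 2.63 (SE 0.14). Of 22 chemokines and cytokines, 4 rose, 11 fell and 7 did not pass, with the same counts when adjusted over the list alone. Cxcl5 (-4.32, SE 0.20), Cxcl14 (-3.92, SE 0.27; -4.54 without GFP-low replicate 1) and Il34 (-2.61, SE 0.18), a ligand of the macrophage receptor CSF1R, fell. Both lists passed camera (adjusted p = 2.50e-07 and 5.09e-04), and neither did with an estimated correlation (adjusted p = 0.532 with an estimated correlation for each). No list passed with an estimated correlation. The test fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, passed for 4 lists: BMP antagonists (adjusted p = 0.0140), complement (0.0340), chemokines and cytokines (0.0400) and other growth factors (0.0400).

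Of 16 genes of the response to tissue dissociation, 5 rose, 1 fell and 10 did not pass, with the same counts when adjusted over the list alone. These counts rest on single libraries: 9 rose and 0 fell without whole mesenchyme, 1 rose and 0 fell without GFP-low replicate 1, and 1 rose and 1 fell without GFP-low replicate 2. Among the 5 were Atf3 (1.09, SE 0.20), Nr4a1 (0.73, SE 0.19) and Ier2 (0.63, SE 0.16). Nr4a1 and Ier2 lost their calls without GFP-low replicate 1 (0.72 and 0.68) or GFP-low replicate 2 (0.47 and 0.42). The list did not pass camera (adjusted p = 0.405), and passed as higher without whole mesenchyme (adjusted p = 0.0165; over all settings 0.0165 to 0.962). The median mitochondrial share was 3.01%, 2.95% and 1.55% in the Cd81-high and 3.98%, 3.65% and 2.51% in the Cd81-low class, in the order of libraries given above.

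Among genes in no list, Pcolce2 (5.37, SE 0.16), which encodes an enhancer of procollagen processing, Sema3d (4.90, SE 0.16), Fez1 (4.72, SE 0.16), Ifi207 (4.64, SE 0.12) and the enkephalin precursor gene Penk (4.46, SE 0.17) were the 5 largest rises. Ifi207 belongs to a multigene family whose members share sequence, so its count is uncertain. Adgrl3 (-6.23, SE 0.22), Syt13 (-6.04, SE 0.30), the transcription factor gene Tbx2 (-5.50, SE 0.14), Igfbp3 (-4.87, SE 0.18) and Fgd6 (-4.13, SE 0.13) were the 5 largest falls. Clusters 3, 4 and 9 held most Cd81-high cells in whole mesenchyme and GFP-low replicate 1, and clusters 0 and 2 in GFP-low replicate 2. Most Cd81-low cells lay in clusters 1 and 7 in whole mesenchyme, 6 in GFP-low replicate 1 and 5 and 13 in GFP-low replicate 2. The count of changed genes fell to 816 without the library as a block, to 1065 with cells thinned to 1000 UMIs and to 243 with cells thinned in the same way and classes set by a Cd81 UMI in place of clusters.

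The third comparison set the Pdgfra-high subepithelial class against both fibroblast classes within whole mesenchyme, which held 1573 of its cells against 21 and 14 in the GFP-low replicates. Pdgfra stood at 1211 CPM (exact Poisson interval 1185 to 1238) in this class, 367 (346 to 389) in the Cd81-high and 277 (269 to 285) in the Cd81-low class. The Pdgfra-high class held the highest levels of Bmp2, Bmp3, Bmp5 and Bmp7 and of the response gene Id1, and the lowest of Grem1, Rspo3 and C3. Bmp3, a divergent BMP ligand, stood at 194 CPM (183 to 205) against 6.52 and 2.91 CPM in the Cd81-high and Cd81-low classes, a 29.7-fold difference from the nearer class. Bmp7 stood at 155 CPM (146 to 165) against 2.93 and 13.3 CPM, and Grem1 at 42.9 CPM (38.1 to 48.2) against 2589 and 385 CPM. The difference has no replicate check.

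Of 201 list genes measured, 20 were at least 4-fold higher and 26 at least 4-fold lower in the Pdgfra-high class than in both fibroblast classes. Among BMP ligands, 4 of 9 were that much higher and none lower: besides Bmp3 and Bmp7, Bmp2 stood at 792 CPM (771 to 814) against 84.4 and 181, and Bmp5 at 673 CPM (654 to 693) against 17.6 and 160. Bmp4 stood at 746 CPM (726 to 767) against 308 and 704, near the Cd81-low class. Among BMP antagonists, Fst stood at 142 CPM (133 to 152) against 17.6 and 2.24. Id1 stood at 719 CPM (699 to 740) against 39.8 and 40.1, and Id3 at 4758 CPM against 1884 and 2871. The median of the BMP ligands over the Cd81-high class lay at percentile 99.98 of 10000 random lists of the same size and expression, and over the Cd81-low class at percentile 99.62. For the BMP response genes the percentiles were 99.96 and 99.85, and for the antagonists 0.33 and 0.28. The random lists drew each gene separately, while members of a list can vary together. Percentiles here and below may thus overstate how far such a list lies apart. The correlation estimated in the second comparison was 0.8945 for the dissociation response and 0.2975 for complement. It was -0.010, -0.024 and -0.064 for the BMP ligands, response genes and antagonists.

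Of 9 Wnt ligands measured, 1 was at least 4-fold higher and 2 lower in the Pdgfra-high class, and the list median lay at percentiles 0.01 and 6.42. Wnt5a stood at 203 CPM (192 to 214) in the Pdgfra-high class against 14.0 and 23.1, and Wnt4 at 207 CPM (196 to 219) against 9.78 and 156. Rspo3 stood at 6.83 CPM (4.98 to 9.14) against 126 and 47.4, Sfrp1 at 129 CPM (121 to 138) against 721 and 1652, and Wnt2, on 3 UMIs, at 0.455 CPM against 3.91 and 5.57, a ratio of 0.116 (0.0211 to 0.431). Wif1, a secreted Wnt inhibitor, stood at 17.1 CPM (14.1 to 20.6) against 1 UMI in the whole Cd81-high class and 3 in the Cd81-low class, a ratio to the Cd81-high class of 52.6 (9.25 to 2096). The R-spondin median lay at percentiles 0 and 0.79. Fgf9 stood at 178 CPM (168 to 189) against 18.3 and 2.30. The activin subunit genes Inhba (78.4 CPM, 71.8 to 85.5, against 7.17 and 3.76) and Inhbb (29.0 CPM, 25.0 to 33.4, against 0.326 and 0.909) were higher too.

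The Pdgfra-high class held more of the basement membrane collagen Col4a5, at 375 CPM (361 to 390) against 46.0 and 58.1, and of Lama5, at 44.9 CPM (39.9 to 50.3) against 0.978 and 6.18. It held less Col8a1 (2.88 CPM, 1.74 to 4.50, against 432 and 20.9) and Col14a1 (47.8 CPM, 42.7 to 53.4, against 1848 and 392). The chemokine gene Ccl11 stood at 125 CPM (117 to 134) against 809 and 1526, the interleukin gene Il33 at 6.98 CPM (5.11 to 9.31) against 179 and 58.8, and C3 at 186 CPM (175 to 196) against 6182 and 1355. The complement median lay at percentile 0 against both classes. The retinoid genes Aldh1a1 (407 CPM, 392 to 423, against 15.3 and 24.7) and Rbp4 (331 CPM, 318 to 346, against 24.1 and 52.9) were higher. The dissociation response list lay at percentiles 99.90 and 99.96, and the median depth of the class was 4003 UMIs with a mitochondrial share of 4.69%.

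**Figure D3:**
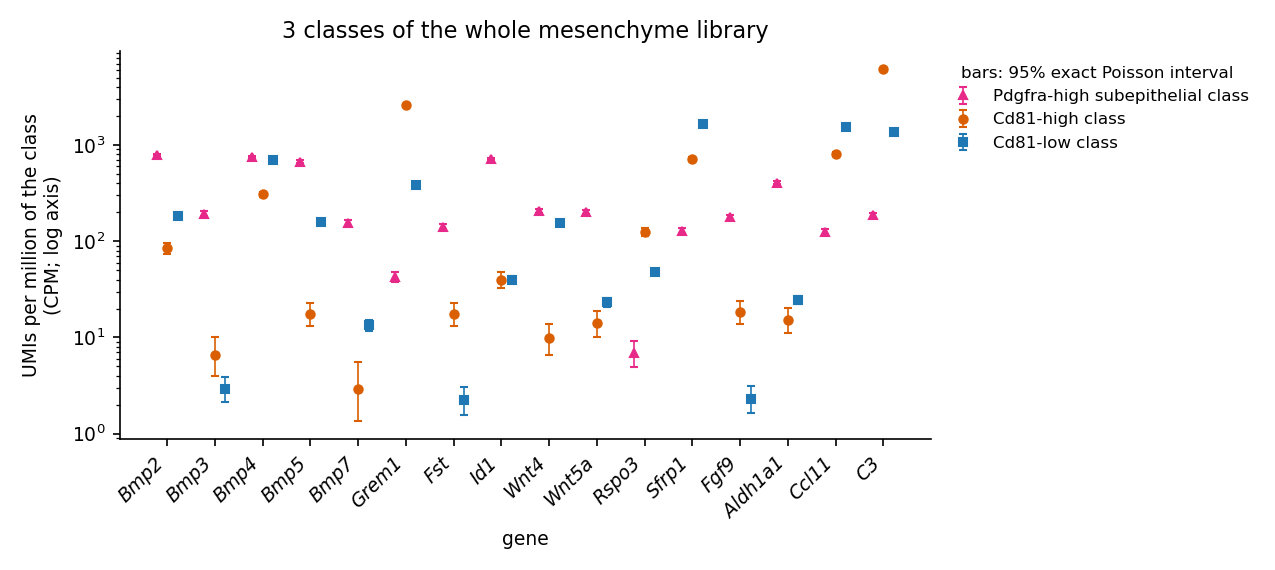
UMI counts scaled to the total of the class (CPM, log axis) of 16 genes (horizontal axis) in the Pdgfra-high, Cd81-high and Cd81-low classes of the whole mesenchyme library, with exact Poisson 95% intervals. Bmp3 lies at 194 CPM in the Pdgfra-high class against 6.52 and 2.91 CPM, and Grem1 at 42.9 against 2589 and 385 CPM.

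The fourth comparison set whole mesenchyme against the GFP-low libraries within each fibroblast class. It had no test, and the libraries differed in sort and in the genotype the labels give, control against the Pdgfra reporter. They also differed in sex transcripts: whole mesenchyme held cells of both sexes, while almost all sexed cells of the GFP-low libraries were male. Few of the genes listed beforehand stood apart, meaning at least 2-fold outside both GFP-low values. In the Cd81-high class 8 of 213 were higher and 4 lower in whole mesenchyme, against 4 higher and 11 lower with only the cells of that library that held Y-linked and no Xist UMIs. In the Cd81-low class 12 of 212 were higher and 2 lower. Grem1 stood at 2589 CPM (2533 to 2647) in the Cd81-high class of whole mesenchyme, between 2285 (2264 to 2305) and 2774 (2755 to 2793) in the GFP-low replicates.

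In the Cd81-high class, Wnt4 stood at 9.78 CPM (6.60 to 14.0) in whole mesenchyme against 1.93 (1.38 to 2.63) and 3.18 (2.59 to 3.88), and Bmp3 at 6.52 CPM (3.98 to 10.1) against 0.434 (0.199 to 0.825) and 0.585 (0.347 to 0.924). Wnt4 and Bmp3 were abundant in other classes of the same library, and blood endothelium there held 6.67 Wnt4 UMIs per 100 cells against 5.15 in Cd81-high cells. Bmp5 and Bmp7 UMIs per cell in blood endothelium were 137% (97.5 to 194%) and 146% (62.5 to 370%) of those in Cd81-high cells, against 1.22% for Grem1. Id1 stood at 39.8 CPM (33.0 to 47.5) against 12.4 (10.9 to 14.0) and 16.1 (14.7 to 17.6), and the EGF receptor ligand gene Areg at 19.6 CPM (14.9 to 25.2) against 3.67 (2.89 to 4.59) and 2.40 (1.89 to 3.02). Free RNA, read from barcodes with few UMIs, also held more of these transcripts in whole mesenchyme: Id1 at 425 CPM against 28.9 and 29.4, Bmp3 at 33.0 against 1.29 and 1.25, and Areg at 73.2 against 30.4 and 22.5. Aldh1a1, an enzyme of retinoic acid synthesis, stood lower, at 15.3 CPM (11.3 to 20.4) against 80.8 (77.0 to 84.8) and 63.0 (60.2 to 65.8). With cells thinned, 1 gene was higher and 7 lower in this class.

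In the Cd81-low class, 3 of 23 chemokines and cytokines were higher in whole mesenchyme, and of 20 other growth factors 2 were higher and 1 lower. Free RNA was also higher in whole mesenchyme for some of these genes, with Cxcl2 at 643 CPM against 40.7 and 122, Ereg at 919.8 against 135 and 204, and Id3 at 4200.5 against 2257 and 2478. It also lay above both GFP-low values for Nr4a1, at 982 CPM against 570.3 and 908, for Ccl2, at 1387 against 788 and 1071, and for Btg2, at 2739 against 1255 and 1808. For Aldh1a1 it was higher, at 113 CPM against 82.7 and 68.1, while the class value was lower. Except Id3, the genes of this class given here were picked after their values were seen. Cxcl2 stood at 964 CPM (949 to 979) against 102 (94.8 to 109) and 320 (309 to 333), Ccl2 at 1437 CPM (1419 to 1456) against 547 (530 to 564) and 515 (500.1 to 531), and Ereg, an EGF receptor ligand gene, at 1625 CPM (1606 to 1645) against 575 (559 to 593) and 602 (586 to 619). Id3 stood at 2871 CPM (2846 to 2897) against 1418 (1391 to 1444) and 1402 (1377 to 1427). Of the dissociation response list, 2 of 16 were higher, Nr4a1 at 1131 CPM (1115 to 1147) against 478 (462 to 493) and 561 (546 to 578), and Btg2 at 4149 CPM (4118 to 4180) against 1964 (1933 to 1996) and 1886 (1857 to 1916). Aldh1a1 stood lower here too, at 24.7 CPM (22.3 to 27.2) against 54.8 (49.7 to 60.2) and 61.6 (56.4 to 67.0).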

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

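The test of whether class differences differ between groups, and the tests on free RNA and dissociation in this part, were chosen only after the result was seen; the test on female cells was written down before it.

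The difference between Cd81-high and Cd81-low fibroblasts was not the same in whole mesenchyme as in the GFP-low libraries for 34 of 6474 genes (edgeR quasi-likelihood interaction test, with the lone whole mesenchyme library assumed to vary like the others), 668 at unadjusted p under 0.05. The spread comes from the GFP-low libraries alone and the count is unstable, from 0 to 137 under the alternatives, so these genes are candidates only. Of the 34, 17 also differed between the classes over all libraries. Wnt4 was among them: its class difference was smaller in whole mesenchyme, with a signed log2 value 2.21 above that of the GFP-low libraries, at -4.00 against -6.48 and -5.99 in GFP-low replicates 1 and 2. The median size of the difference over the 34 genes was 1.32 on the log2 scale (quartiles 1.12 to 1.59).

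Female cells in whole mesenchyme were 1 explanation tested. With only the cells of that library that held Y-linked and no Xist UMIs, the median size over the 34 genes was 101.06% of its value with all cells (1.33 against 1.32, quartiles 1.07 to 1.58), which argues against female cells as the cause, although 0 genes passed the edgeR test there (562 at unadjusted p under 0.05) on a Cd81-high sum of 188 in place of 582 cells. The median size held while the calls ended, and why they ended was not tested. Free RNA from burst cells pulls both classes toward its own level and cannot by itself turn a difference around where that level lies between the values of the classes. Of the 34 genes, 16 had turned direction in whole mesenchyme beyond counting error, and for 9 of these the free RNA level lay between the class values. For 2 of the 9, Trib1 and Hes1, it did so beyond counting error. At most 2 such genes was the outcome set, after the result was seen, for free RNA alone as the cause. The count met that outcome, but an outcome set after the result was seen cannot decide on free RNA over the 34 genes. The UMIs of blood endothelium markers also limit the share of free RNA in each class, to at most 4.99% of the Cd81-high and 5.54% of the Cd81-low UMIs of that library, if free RNA in cells has the profile of barcodes with few UMIs. With any share up to these removed, 16 genes stayed turned beyond counting error. If the limits hold, this argues against free RNA of whole mesenchyme alone for these 16. However, Wnt4, Bmp5 and Bmp7 stood at 9.78, 17.6 and 2.93 CPM in Cd81-high cells of that library. In free RNA they stood at 117, 212 and 36.3 CPM. Were free RNA their source, its share would lie above the limit for that class. The limits are therefore uncertain, and free RNA alone stays open for these 16 genes and the others, except Trib1 and Hes1. Their free RNA levels (258.7 and 1871.4 CPM) lay between the Cd81-high (187.7 and 1498.5) and Cd81-low (390.7 and 2017.8) values of whole mesenchyme. This argues against free RNA alone for these 2 at any share, if free RNA in cells has the profile given above. For Wnt4 free RNA stays a candidate source: blood endothelium of the same library held 129.33% (81.1 to 210%) as many Wnt4 UMIs per cell as the Cd81-high class. A stronger dissociation response of the Cd81-low cells of whole mesenchyme also stays open. For 16 of the 16 genes of the dissociation response list the difference lay below 0, with a median of -0.7242, and Fosb was the 1 list member among the 34 genes. The sorts and the genotypes of the libraries differ in the same way and were not tested.

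Xist, the transcript of the inactive X chromosome in female cells, gave 13604 UMIs in whole mesenchyme against 5 and 2 in GFP-low replicates 1 and 2. It stood out as a signal outside the comparisons. Transcripts of 4 Y-linked genes were found in each library, with 4876, 5563 and 8785 UMIs. In whole mesenchyme 34.2% of cells held Xist and no Y-linked UMIs, 35.5% held Y-linked UMIs alone, 2.96% both and 27.3% neither, so that library held cells of both sexes, and almost all sexed cells of the GFP-low libraries were male. Of the cells with UMIs of 1 sex alone, Xist cells made up 57.8% of the Cd81-high, 45.2% of the Cd81-low and 47.3% of the Pdgfra-high class.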

How the results depend on the processing

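The doublet score alternative and those by sex transcripts, all alternatives for the Pi16 comparison and all for the differences between groups were chosen only after the results were seen. Over the 70 named genes and 24 alternatives, some of which could not test every gene, 1586 values kept their direction and side of the threshold, 60 no longer passed, 2 newly passed (Id3 without whole mesenchyme, a fit that is counted again as GFP-low libraries only) and 2 reversed (Wnt2b at 0.050 and Id4 at 0.15 with classes set by a Cd81 UMI); 24 of the 60 arose under that same setting, which also thins cells to 1000 UMIs. The count of genes changed between Cd81-high and Cd81-low fibroblasts was 1935; it was 816 without the library block, 243 with classes set by a Cd81 UMI in thinned cells, 1065 of 5405 tested with cells thinned to 1000 UMIs, 3703 of 12818 with all genes tested, 1417 with DESeq2, and 1362 to 2137 with 1 library left out. Fewer counts lie behind the thinned value and more genes behind that with all genes. List tests past the threshold numbered 3, against 6 with GFP-low libraries only, 7 with classes set by a Cd81 UMI, 5 with thinned cells, 0 with an estimated correlation and 3 to 6 with 1 library left out. With an estimated correlation BMP antagonists, chemokines and complement each stood at adjusted p = 0.532 (limma camera; over all settings from 5.57e-06, 7.81e-10 and 4.99e-10 up to that value). Of the CPM values of the Pdgfra-high class over all alternatives, 26 moved outside their 95% counting interval and 64 did not. For those of the fibroblast classes of whole mesenchyme 57 did and 95 did not. Shares moved little beside the gap between groups. In whole mesenchyme the Cd81-high share was 9.59% at 2000 UMIs, 9.62% at 10% mitochondrial UMIs, 9.93% with each library clustered on its own and 9.47% without the highest doublet scores; the Cd81-low share was 51.7% at 2000 UMIs, 46.9% at 10% mitochondrial UMIs, and 49.8% and 46.7% at resolutions 0.5 and 2. Its Pdgfra-high share was 20.7% at 2000 UMIs and 21.2% at 10% mitochondrial UMIs, and its Cd81-high share of both fibroblast classes 17.0% at 10% mitochondrial UMIs, 16.8% clustered on its own and 16.4% without the highest doublet scores. In GFP-low replicate 2 the Cd81-high share was 75.3% at 2000 UMIs and 76.0% at resolution 0.5, and 77.0% of both classes there. In GFP-low replicate 1 it was 70.5% with clustering on all genes. Of list genes standing apart within the Cd81-high class, 1 was higher and 7 lower with thinned cells, and 4 and 11 with Y-linked cells only; within the Cd81-low class 1 was lower at 2000 UMIs and 4 with Y-linked cells only. The Pi16 comparison gave 906 genes, 161 without the library block and 366 to 1030 with 1 library left out (653 without GFP-low replicate 1, 366 without GFP-low replicate 2). Class differences that differed between groups numbered 34, against 0 with Y-linked cells only (562 at unadjusted p under 0.05, edgeR), 0 with Xist cells only (540), 11 with thinned cells, 137 with equal cell numbers and 6 at 10% mitochondrial UMIs. Except where a reason is given, the cause was not tested. Depth limits how many genes can be tested, 5405 with thinned cells in place of 6474.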

Other observations

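The Pi16 comparison, and the tests on the GFP gate, the limits on cells and the naming of clusters, and the other splits for the 2 fibroblast classes, were chosen only after the results were seen; the tests on depth and on other splits for Pi16 were written down before.

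A cluster rich in Pi16, a peptidase inhibitor gene of fibroblasts around vessels, made up 6.53% of the Cd81-high cells of whole mesenchyme, 6.49% in GFP-low replicate 1 and 11.0% in GFP-low replicate 2. It held far less of the BMP antagonist gene Grem1 than the other Cd81-high cells (-3.25 on the log2 scale, SE 0.22, adjusted p = 1.08e-10, edgeR quasi-likelihood test, lower in 3 of 3 libraries). Of 5539 genes tested, 425 were higher and 481 lower in it. The cluster held 38 cells in whole mesenchyme, 226 in GFP-low replicate 1 and 456 in GFP-low replicate 2. It was formed from the same cells, so tested genes that vary with the clustering genes differ in part by construction. The p-values take the cluster as given. Gdf10 (-6.08), Rspo2 (-4.02), Il34 (-4.52) and Spon1 (-3.98) were lower, as were Gdf6 (-2.57), Kitl (-2.96), Mgp (-2.53), Sfrp1 (-1.87) and Rspo3 (-0.94). Wnt10b (3.77, SE 0.21), Wnt2 (3.00), Nov (3.76), Sfrp4 (2.79) and Fst (1.77) were higher, with Fn1 (1.44), Efemp1 (1.49), Mfap5 (1.39), Ccl2 (1.29) and Fgf18 (1.26). By list, 11 of 19 matrix glycoproteins were higher and 3 lower, 0 of 9 Hedgehog response genes higher and 5 lower, and 1 of 10 complement genes higher and 4 lower. Without GFP-low replicate 2 the count of changed genes was 366 in place of 906. The genes named here were picked after their values were seen. The 6 sums allow 10 splits, too few for a share under 0.05: the real split gave 906 genes, the highest other 0, so 1 of 10 gave as many. Splits with 1 sum of each library on each side, which keep the pairing, are fewer still.

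Cell types other than fibroblasts held several of the listed signals in whole mesenchyme. Glia held 287 CPM (229 to 356) of the BMP antagonist gene Sostdc1 and 844 CPM (741 to 956) of the growth factor gene Pdgfa, against 9.88 CPM of Pdgfa in the Cd81-low and 13.4 CPM in the Pdgfra-high class. Blood endothelium held 1526 CPM (1479 to 1575) of Id1 and 680 CPM (648 to 713) of Eng, lymphatic endothelium 195 CPM (140 to 263) of Il7, and glia 76.1 CPM (47.7 to 115) of Wnt6. An unnamed cluster of 101 cells in whole mesenchyme, 35 in GFP-low replicate 1 and 17 in GFP-low replicate 2 carried Wnt4 at 548, 673 and 605 CPM and Nrg1 at 1040, 485 and 563 CPM. Its Adamdec1 level, 16135, 15077 and 16211 CPM, lay above that of the Cd81-low class, and Cd81 stood at 21.1, 21.9 and 7.04 CPM. By Adamdec1 and Cd81 it resembled Cd81-low fibroblasts. Nrg1 and Agt, the latter at 328, 313 and 464 CPM, were among the markers fixed for the Pdgfra-high class. Foxl1 and Sox6, of the same set, stood at only 4.45 and 8.90 CPM in whole mesenchyme. The markers thus conflicted. Another unnamed cluster, with 410 of its cells in GFP-low replicate 2, was shallow.

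For the genes changed between Cd81-high and Cd81-low fibroblasts, unequal depth of the classes was tested by thinning every cell to 1000 UMIs. The median ratio of the thinned to the full log2 difference over the called genes was 0.9916 (quartiles 0.8672 to 1.127, 1623 of 1629 with the same sign). Random thinning with the classes kept leaves the expected share of each gene in a class unchanged. The ratio therefore cannot decide whether depth shaped the classes or their differences. The 6 sums allow 10 splits, too few for a share under 0.05: the real split gave 1935 genes and the highest other 0, so 1 of 10 gave as many. Splits with 1 sum of each library on each side, which keep the pairing, are fewer still. With an equal number of cells drawn at random per class and library the median ratio was 0.9774 (1720 of 1721 with the same sign), which has the same limit. No biological explanation was tested.

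The Cd81-high share of both fibroblast classes was far lower in whole mesenchyme than in the GFP-low libraries, 15.1% against 75.5% in GFP-low replicate 2. The limits on UMIs and mitochondrial share do not account for it, since the highest value in whole mesenchyme under other limits was 17.027% and the lowest GFP-low value 74.125%. Nor does the boundary between the classes, since the share of these cells with a Cd81 UMI after thinning was at least 3.9968 times higher in the GFP-low libraries. That share covers only cells named as either class, so it cannot decide on clusters left out by the naming. The GFP gate leaving out more Cd81-low than Cd81-high cells stays open. That explanation would have the Cd81-low cells outside the gate, and Pdgfra transcripts in Cd81-low cells of whole mesenchyme were 0.75471 (0.707 to 0.806) of those in Cd81-high cells, a candidate reason if the gate has a lower limit. Pdgfra transcripts were also lower in the GFP-low libraries than in whole mesenchyme. They stood at 184 and 148 CPM in GFP-low replicates 1 and 2 against 367 in Cd81-high cells. In Cd81-low cells they stood at 112 and 144 against 277 CPM. The reason was not tested. The reporter protein was not measured in these counts, and a difference of genotype or animal was not tested.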
